A study of Drosophila melanogaster with 47 samples.

How the data were processed

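RNA was measured in midguts and sorted midgut cells of adult female Drosophila melanogaster. Of 47 samples, 32 were analysed: 4 mated and 4 unmated libraries each of esg-Gal4 whole guts, esg-positive progenitor cells, Actin driver controls and Actin driver EcR RNAi. Per the labels' protocols, mating lasted 48 h, the Actin flies were held 5 days at 29 °C for RNAi and mated at 25 °C, and libraries were made from poly(A)-selected RNA with a directional kit. The labels give replicates as pools of guts, and the p-values measure the spread between these pools. The 15 samples of the Myo1A driver were not analysed here, because the file named for them holds the whole gut columns with identical values. In the files used, 16 further columns were not used here.

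The deposited files give counts per gene, which the authors made, per the submitters' processing notes, with STAR, HTSeq and DESeq2 on the builds BDGP6 and dm6. Tool versions and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes on either strand cannot be assigned with certainty. The tables hold 10635, 11128 and 10406 genes for whole gut, progenitors and Actin, with 501, 1059 and 594 further entries for transposable elements, which were left out of the gene tests. Gene symbols and identifiers are those of the files. Coordinates were read from the BDGP6.54 annotation by gene identifier and are 1-based.

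Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, scaled by trimmed mean of M values (TMM), and fitted with robust quasi-likelihood dispersions. Each comparison was tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05, and this is the adjusted p meant for single genes throughout. Standard errors are the size of the log2 fold change divided by the square root of its F statistic, so they are not independent of the p-values. Whole gut and progenitors were each fitted alone, all 16 Actin libraries together, and whole gut and progenitors together for the difference of their mating responses. The comparisons were mating in each kind of material, genotype within each mating state, the interaction of genotype and mating, and the difference of mating responses. A difference between Actin control and whole gut, comparisons of the whole gut score with progenitors, and overlaps of calls of the mating responses with that of the libraries labelled EcR RNAi and of the genotype comparisons in both mating states were added after the data had been seen.

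Fixed gene lists, 21 for processes and 10 for cell types, were written before the data were examined, as were the comparisons and alternatives other than those named as added, and the rule for naming genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with all other genes, while fry asks whether its genes move on balance 1 way. The adjusted p of a list is camera's, adjusted over the lists of that comparison. The rule named EcR, the 5 highest and 5 lowest called genes by fold change with a mean log2 CPM of at least 3 and no overlap between groups, and for each list the 3 called members with the smallest adjusted p. For 4 against 4 libraries chance gives no overlap in 2.86% of genes. From the genes so named a selection is printed.

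Each setting was changed alone: DESeq2 1.42.0 in place of edgeR, its size factors, upper quartile scaling, no filter, a stricter filter with a minimum count of 50, the replicate number as a block, only the compared groups in the fit, and leaving out each library in turn. Leaving out unmated progenitor libraries 1 and 4 together was added later. Up to 100 splits of the libraries into other groups were fitted for each comparison. The whole gut score was compared with exact two-sided permutation tests.

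The procedure was tested on simulated counts with known changes, drawn at the real means and library sizes. By edgeR the share of changed genes recovered at 1.5-fold, 2-fold and 3-fold was 20.9%, 64.2% and 84.8% for mating in whole guts, 41.8%, 74.6% and 84.8% in progenitors, 55.2%, 64.2% and 80.3% in Actin controls, and 50.7%, 76.1% and 90.9% in libraries labelled EcR RNAi. It was 61.2%, 80.6% and 90.9% for genotype in unmated guts, 62.7%, 83.6% and 87.9% in mated guts, and 17.9%, 56.7% and 75.8% for the interaction. It was 11.9%, 61.2% and 80.3% for the difference between progenitors and whole gut, and 7.46%, 44.8% and 69.7% for the difference between Actin control and whole gut. Unchanged genes made up 0.641% to 6.61% of edgeR's calls and 8.40% to 20.9% of DESeq2's. Simulated genes varied independently of each other, and libraries of a group shared no further structure. These shares need not hold in the real comparisons.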

Results

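The study asked how mating changes the midgut of adult female Drosophila melanogaster, and whether ecdysone signalling takes part. Mated females had been housed with males for 48 h, and unmated females of the same age and genotype had been kept away from males. Poly(A) RNA was sequenced from 4 kinds of material, each as 4 mated and 4 unmated libraries. Whole midguts and sorted esg-positive cells came from flies carrying esg-Gal4, a driver active in the intestinal progenitors, that is stem cells and their undifferentiated daughters. Whole midguts also came from flies carrying the ubiquitous Actin driver, either as control or with an RNAi construct against EcR, the gene of the ecdysone receptor. A whole gut library was a pool of 15 guts and a sorted library came from 100 to 150 guts. Total counts per library were 17005386 to 24538084 in mated and 13718418 to 22350830 in unmated whole guts. They were 31362803 to 44260161 in mated and 34284770 to 37253762 in unmated progenitors, and 21608238 to 28320408 in mated and 21315098 to 29820841 in unmated Actin controls. In the libraries labelled EcR RNAi they were 22639143 to 25326961 when mated and 19383292 to 25779384 when unmated. Levels are given as group means ± SD in CPM, with n = 4 libraries per group. CPM are counts scaled to the library size after its adjustment by the TMM factor, not to the library total alone. Changes are given as log2 fold changes with their standard errors (SE).

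EcR, the target of the RNAi, was measured first in every group. EcR (FBgn0000546) lies on chromosome 2R from 6087873 to 6169087, minus strand, and shares positions with other genes on both strands. Its level was 8.28 ± 0.94 CPM in mated and 8.07 ± 1.04 CPM in unmated Actin controls (SD, n = 4). In the libraries labelled EcR RNAi it was 9.57 ± 1.15 CPM when mated and 12.9 ± 1.28 CPM when unmated. EcR was thus higher, not lower, in the unmated libraries labelled EcR RNAi, with a log2 fold change of 0.67 (SE 0.11, adjusted p = 0.00125). In the mated libraries the difference was 0.21 (SE 0.11, adjusted p = 0.34). The label EcR RNAi is therefore used as given, and a lower EcR transcript level was not detected in the libraries labelled EcR RNAi in either mating state. In the esg-Gal4 material EcR was at 13.6 ± 2.01 CPM in mated and 12.5 ± 1.98 CPM in unmated whole guts, and at 53.9 ± 6.32 CPM in mated and 56.8 ± 8.70 CPM in unmated progenitors. Neither mating difference passed the test, with adjusted p-values of 0.749 and 0.63.

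In whole guts as labelled, mating went with lower transcripts of digestive proteases and of muscle. Transcripts of some carbohydrate digestion and sterol uptake genes were higher. All whole gut directions rest on the mated and unmated labels as deposited, and an exchange of these labels was not excluded. Jon25Bii (FBgn0031654; 2L, 4952243 to 4953136, minus strand), a serine protease of the Jonah family, fell from 5377 ± 1095 CPM in unmated to 789 ± 177 CPM in mated guts, a log2 fold change of -2.77 (SE 0.21, adjusted p = 1.82e-04). The most abundant protease named here, Jon65Aiii, fell from 25469 ± 2791 to 8001 ± 734 CPM, and yip7 from 18044 ± 1457 to 6035 ± 549 CPM. Amyrel (FBgn0020506; 2R, 16651095 to 16652699, minus strand), a relative of amylase, rose from 6.62 ± 3.99 to 236 ± 100 CPM, a log2 fold change of 5.18 (SE 0.58, adjusted p = 0.00306). The glucosidase gene tobi (FBgn0261575; 3R, 25344761 to 25346921, minus strand), known as a target of brain insulin, rose from 1216 ± 441 to 5550.2 ± 567 CPM.

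Of 30 digestive proteases, 18 fell and 12 did not pass the test, and 20 fell when adjusted over the list alone. Their median log2 fold change was -0.99 and the competitive list test gave an adjusted p of 7.81e-48 (adjusted p = 0.0371 with an estimated correlation). Jon25B and Jon65A genes are related copies, and sharing of reads among them was not measured, so their single values are uncertain. Of 11 visceral muscle markers, 7 fell, 9 when adjusted over the list alone. Among them were Mlc2 (386 ± 45.5 to 201 ± 10 CPM), wupA and Act87E (159 ± 11.6 to 45.5 ± 16.6 CPM), which encode a myosin light chain, a troponin and an actin. The muscle list had an adjusted p of 1.68e-14 (adjusted p = 0.129 with an estimated correlation). Carbohydrate digestion genes went both ways: 6 of 21 rose and 4 fell, 10 and 5 when adjusted over the list alone. The lysosomal mannosidases LManI (305 ± 28.7 to 181 ± 9.41 CPM) and LManII (2133 ± 170 to 975 ± 194 CPM) were among those that fell. The list had an adjusted p of 0.0294 (adjusted p = 0.734 with an estimated correlation). Its call was lost with the replicate block (camera adjusted p = 0.0773). Of 9 sterol uptake genes, 3 rose and 1 fell, the same counts as when adjusted over the list alone, and Npc1b, needed for sterol absorption, rose from 525 ± 105 to 1421 ± 275 CPM. The list's adjusted p was 0.0325 (adjusted p = 0.468 with an estimated correlation, and camera adjusted p = 0.0605 with the replicate block). Of 12 lipases, 1 rose and 3 fell, 2 and 5 when adjusted over the list alone. The genes bmm, the brummer triglyceride lipase (346 ± 63.7 to 114 ± 25.7 CPM), Lip4 (40.3 ± 7.41 to 17.5 ± 2.65 CPM) and CG17192 (3172 ± 563 to 1047 ± 330 CPM) fell. The lipase list had a median of -0.24, a mean of 0.15 and an adjusted p of 0.0192 in the lower direction (adjusted p = 0.625 with an estimated correlation). This call too was lost with the replicate block (camera adjusted p = 0.113). Men, which encodes malic enzyme, rose from 167 ± 8.34 to 282 ± 21.9 CPM, and the zinc transporter gene Zip42C.1 from 6.15 ± 1.26 to 15.3 ± 3.46 CPM. Of the alkaline phosphatase genes, Alp10 fell from 1832 ± 246 to 388 ± 59.9 CPM and Alp2 from 76.7 ± 19.3 to 12.2 ± 7.43 CPM. The trypsin gene Try29F, which overlaps another gene on its strand, rose from 8.16 ± 4.08 to 58.7 ± 18.0 CPM. Of 22 detoxification genes 4 rose, 5 when adjusted over the list alone (median 0.31, adjusted p = 0.00167, and adjusted p = 0.625 with an estimated correlation), and of 14 fatty acid oxidation genes 1 rose, 2 when adjusted over the list alone (median 0.16, adjusted p = 0.0192, and adjusted p = 0.734 with an estimated correlation).

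Other lists passed the list test in whole guts with 0 members called by edgeR. The 9 heat shock genes had a median of -1.60 (adjusted p = 4.15e-04, and adjusted p = 0.625 with an estimated correlation), with 3 lower at an unadjusted p under 0.05, 1 lower when adjusted over the list alone and 3 lower by DESeq2. The 9 haemocyte markers had a median of 0.66 (adjusted p = 0.0294, and adjusted p = 0.734 with an estimated correlation), with 1 higher at an unadjusted p under 0.05, 0 when adjusted over the list alone and 1 higher by DESeq2. The 80 ribosomal protein genes had a median of 0.28 (adjusted p = 1.27e-06, and adjusted p = 0.734 with an estimated correlation), with 8 higher at an unadjusted p under 0.05, and 0 when adjusted over the list alone and by DESeq2. The 58 respiratory chain genes had a median of -0.13 (adjusted p = 0.00121, and adjusted p = 0.734 with an estimated correlation), with 1 higher and 4 lower at an unadjusted p under 0.05, 0 when adjusted over the list alone and 1 lower by DESeq2.

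In all, 197 genes were higher and 179 lower in mated whole guts of 8833 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and upper quartile scaling gave 143 higher and 221 lower. The count was 202 without mated library 4, 195 without unmated library 3 and 217 without unmated library 4.

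**Figure D1:**
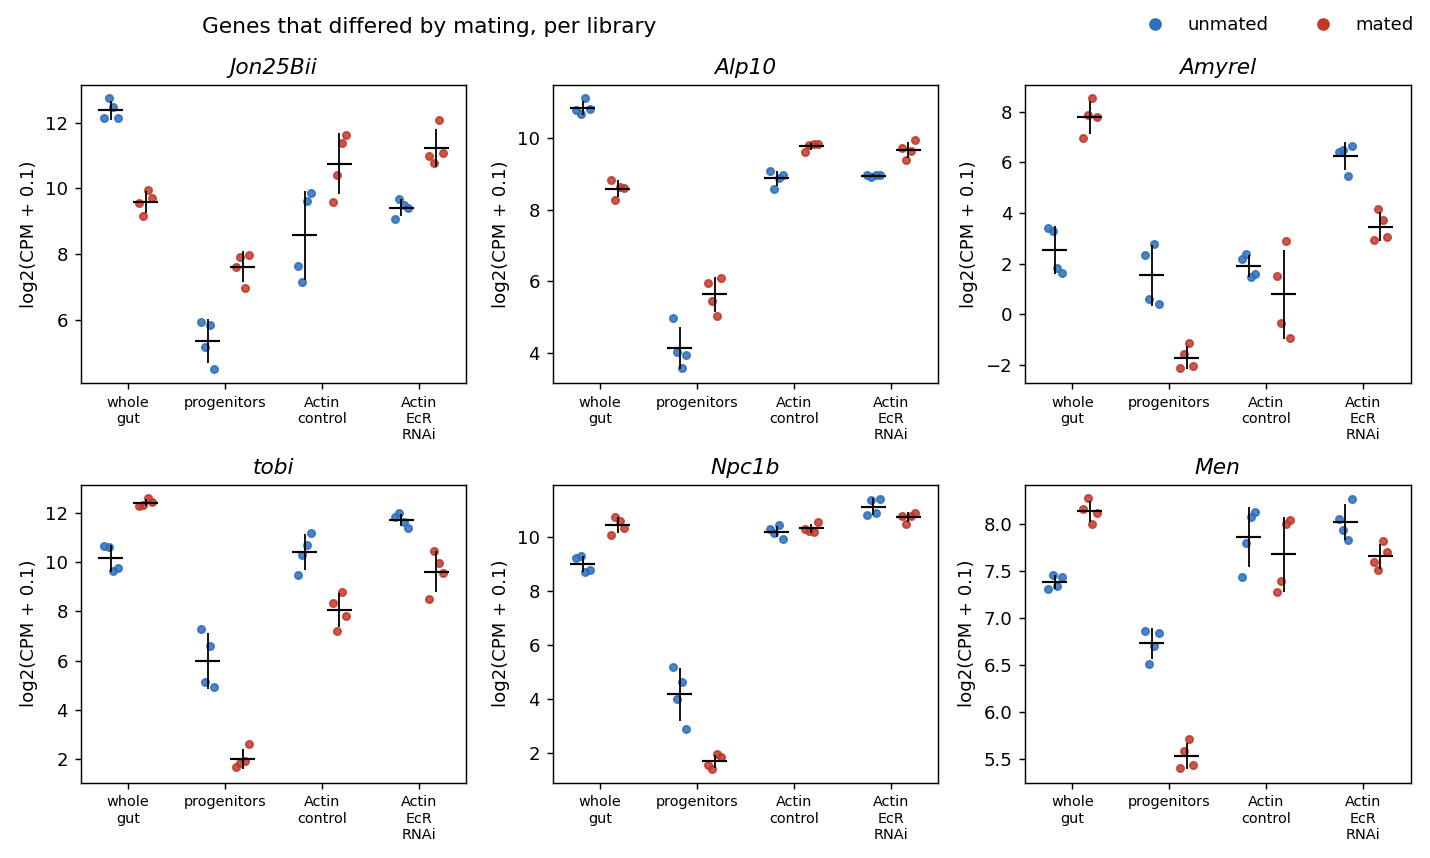
Level of 6 genes in each library on a log2(CPM + 0.1) axis, for unmated (blue) and mated (red) libraries of the 4 kinds of material, with horizontal bars at the mean and vertical bars of 1 SD (n = 4). By the labels as deposited, Jon25Bii and Alp10 fell with mating in the whole gut and rose in progenitors. By the same labels Amyrel, tobi, Npc1b and Men rose in the whole gut and fell in progenitors. Transcripts of other cells in the sorts were not told apart from those of progenitors.

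In sorted progenitors, mating went with lower transcripts of heat shock, detoxification and unfolded protein response genes, and with higher transcripts of cell cycle genes. Hsp23 (FBgn0001224; 3L, 9381882 to 9382765, plus strand), a small heat shock protein gene, fell from 7494 ± 4240 CPM in unmated to 458 ± 179 CPM in mated progenitors, a log2 fold change of -4.03 (SE 0.50, adjusted p = 0.00259). The glutathione transferase gene GstD2 (FBgn0010038; 3R, 12371971 to 12372704, plus strand) fell from 296 ± 157 to 18.1 ± 6.52 CPM (log2 fold change -4.02, SE 0.44, adjusted p = 0.0021). The trehalose transporter gene Tret1-1 fell from 470 ± 171 to 33.2 ± 7.63 CPM, and upd3, a cytokine of the JAK/STAT pathway, from 258 ± 82.9 to 80.1 ± 21.7 CPM. CycB, a mitotic cyclin, rose from 56.3 ± 12.7 to 87.0 ± 6.98 CPM (log2 fold change 0.63, SE 0.15, adjusted p = 0.0117).

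All 12 tested heat shock genes fell, also when adjusted over the list alone, with a median log2 fold change of -2.63 and an adjusted p of 2.03e-15 (adjusted p = 0.468 with an estimated correlation). Hsp27 fell from 5218 ± 2739 to 474 ± 118 CPM. The mean log2 CPM of these genes was 7.23 to 7.93 in the mated libraries and 10.9, 10.2, 9.06 and 10.5 in unmated libraries 1 to 4. Of 24 detoxification genes, 19 fell and 1 rose, 20 and 1 when adjusted over the list alone, with a median of -1.63 and an adjusted p of 6.72e-13 (adjusted p = 0.468 with an estimated correlation). GstD genes are related members of the same family, and sharing of reads among them was not measured. Cyp6g1, a cytochrome P450 gene, fell from 16.6 ± 2.73 to 4.40 ± 0.98 CPM. Of 10 unfolded protein response genes, 7 fell, also when adjusted over the list alone. The endoplasmic reticulum chaperone Hsc70-3 went from 2714 ± 1199 to 747 ± 84.9 CPM and the transcription factor Xbp1 from 1045 ± 268 to 513 ± 15.2 CPM. This list had an adjusted p of 0.00271 (adjusted p = 0.48 with an estimated correlation). Of 16 growth signalling genes, 10 fell and 2 rose, the same when adjusted over the list alone (adjusted p = 0.0114, and adjusted p = 0.48 with an estimated correlation). Besides upd3, rho, whose product releases EGF receptor ligands, fell from 14.2 ± 7.39 to 2.96 ± 1.16 CPM, and pnt, an EGF pathway transcription factor that overlaps another gene on its strand, from 156 ± 4.88 to 108 ± 15.9 CPM. Of 8 insulin and TOR genes, 4 fell, 5 when adjusted over the list alone (adjusted p = 0.0119, and adjusted p = 0.48 with an estimated correlation). Thor, the translation inhibitor 4E-BP, went from 519.7 ± 113 to 298 ± 51.7 CPM, and ImpL2, a secreted insulin antagonist that overlaps another gene on its strand, from 39.8 ± 14.1 to 9.05 ± 3.23 CPM. Of 15 nutrient transporters, 7 fell, 8 when adjusted over the list alone, including the amino acid transporter path (2332 ± 727 to 778 ± 33.4 CPM). The list had an adjusted p of 0.00268 (adjusted p = 0.48 with an estimated correlation). Lsd-2, a lipid droplet protein gene, fell from 1599 ± 628 to 395 ± 77.7 CPM. In its list of 19 lipid synthesis genes, 9 fell and 1 rose, 9 and 2 when adjusted over the list alone (adjusted p = 0.0455, and adjusted p = 0.48 with an estimated correlation). Ldh, lactate dehydrogenase, fell from 387 ± 125 to 98.6 ± 22.3 CPM and Hex-A, a hexokinase, from 415 ± 154 to 164 ± 12.4 CPM. Of 10 immune genes 5 fell, 6 when adjusted over the list alone (adjusted p = 0.00475, and adjusted p = 0.468 with an estimated correlation). The NF-kappaB gene Rel went from 977 ± 257 to 277 ± 97.9 CPM and PGRP-SD from 50.7 ± 10.6 to 13.6 ± 3.84 CPM. Both overlap another gene on their strand. The count of lower immune genes was 3 without mated library 2 or 4 or unmated library 2. Without unmated libraries 1 and 4, an alternative added after the data had been seen, 6 growth signalling and 4 lipid synthesis genes fell.

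Of 35 cell cycle genes, 22 rose and 1 fell, 24 and 1 when adjusted over the list alone, with a median of 0.42 and an adjusted p of 4.05e-07 (adjusted p = 0.584 with an estimated correlation). The anillin gene scra rose from 159 ± 18.4 to 211 ± 8.78 CPM and the kinesin gene ncd from 49.3 ± 8.52 to 71.7 ± 5.08 CPM. Of 81 ribosomal protein genes, 76 fell, 78 when adjusted over the list alone, by small amounts (median -0.29, adjusted p = 2.52e-09, and adjusted p = 0.606 with an estimated correlation). RpL4 went from 5629 ± 489 to 4379 ± 290.1 CPM. Both counts depended on single libraries: the cell cycle genes called higher were 12, 11 and 14 without mated libraries 1, 4 and 3 and 10 without unmated library 4, and the ribosomal protein genes called lower were 22 without mated library 3 or 4 and 24 without unmated library 4. Without unmated libraries 1 and 4, 7 cell cycle genes rose (median 0.28), and 0 ribosomal protein genes were called by edgeR (median -0.20, 59 lower at an unadjusted p under 0.05). Of 12 progenitor markers, 3 rose and 5 fell, the same when adjusted over the list alone. The Notch targets E(spl)malpha-BFM and E(spl)mbeta-HLH were among those that fell. The list as a whole did not pass the test (adjusted p = 0.653). Markers of cells outside the sort moved too. Of 18 enteroendocrine markers 8 fell, also when adjusted over the list alone (adjusted p = 0.00643, and adjusted p = 0.544 with an estimated correlation). Of 7 ovary markers 6 fell, also when adjusted over the list alone (adjusted p = 0.00258, and adjusted p = 0.48 with an estimated correlation). The ovary marker psd went from 5.37 ± 2.26 to 1.24 ± 0.29 CPM. Enteroendocrine markers called lower were 5, 3 and 5 without mated libraries 1, 2 and 4, 4 without unmated library 1 or 4 and 1 without both of these, where ovary markers were 2. Of 12 enterocyte markers 3 fell, also when adjusted over the list alone (adjusted p = 0.146), including mex1 from 43.4 ± 18.4 to 17.7 ± 2.44 CPM. Of 28 digestive proteases 3 rose and 2 fell, 2 and 1 when adjusted over the list alone, with a median of -0.11, a mean of 0.03 and an adjusted p of 0.59 in the higher direction. Of 20 carbohydrate digestion genes 11 fell and 3 rose, 12 and 4 when adjusted over the list alone (median -0.93, adjusted p = 0.0744), and 7 fell without mated library 2 or unmated library 1. Of 9 lipases 5 fell and 1 rose, also when adjusted over the list alone (median -0.97, adjusted p = 0.0806). Among single genes that rose, Jon25Bii went from 44.4 ± 18.5 to 204 ± 57.6 CPM, Alp9 from 12.9 ± 5.16 to 36.9 ± 12.2 CPM and CG17192 from 33.6 ± 19.0 to 107 ± 32.6 CPM. The genes tobi (80.2 ± 60 to 4.00 ± 1.32 CPM) and CG11825 (45.4 ± 21.1 to 1.35 ± 0.33 CPM) were among the genes that fell most.

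In all, 1724 genes were higher and 1903 lower in mated progenitors of 9025 tested. The large changes ran mostly 1 way, with 63 called genes higher and 899 lower by over 2-fold. Upper quartile scaling gave 2024 higher and 1820 lower. Without unmated library 4 the count of called genes was 2248. Without unmated libraries 1 and 4, an alternative added after the data had been seen, it was 1302. At that setting RpL4 lost its call (adjusted p = 0.0533).

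**Figure D2:**
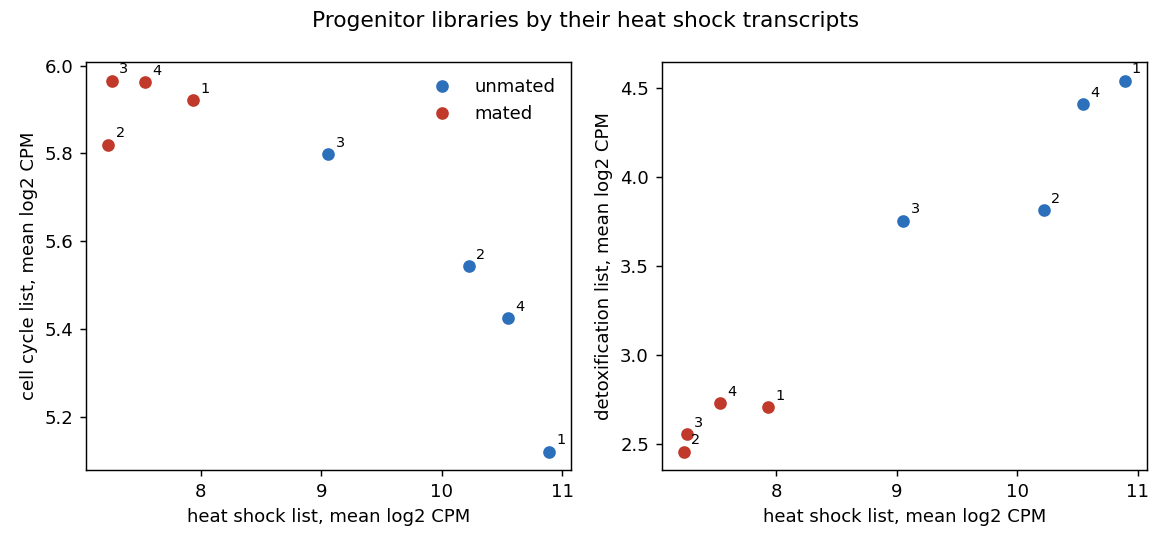
Mean log2 CPM of the cell cycle list (left) and of the detoxification list (right) against that of the heat shock list, 1 point per progenitor library with its replicate number, unmated in blue and mated in red. The 4 unmated libraries spread from 9.06 to 10.9 on the heat shock axis and the mated ones from 7.23 to 7.93.

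Mated guts of Actin control flies had lower transcripts of ribosomal proteins and of several starch and sugar digesting enzymes, and higher transcripts of the amino acid transporter genes path and slif. The glucosidase gene tobi fell from 1506 ± 686 CPM in unmated to 286 ± 129 CPM in mated guts, a log2 fold change of -2.39 (SE 0.45, adjusted p = 0.00913). Cyp28d1 (FBgn0031689; 2L, 5210460 to 5212445, plus strand), a cytochrome P450 gene, fell from 264 ± 31.5 to 66.4 ± 3.55 CPM (log2 fold change -1.99, SE 0.22, adjusted p = 5.28e-04). CG4563 (FBgn0035006; 2R, 24451084 to 24453040, minus strand) rose from 155 ± 23.7 to 433 ± 20.5 CPM (log2 fold change 1.48, SE 0.20, adjusted p = 0.00213). The genes path and slif rose from 119 ± 15.7 to 181 ± 15.1 CPM and from 186 ± 36.8 to 355 ± 28.5 CPM.

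Of 80 ribosomal protein genes, 76 fell, 77 when adjusted over the list alone, with a median log2 fold change of -0.37 and an adjusted p of 5.93e-42 (adjusted p = 0.585 with an estimated correlation). RpS21 went from 581 ± 44.1 to 421 ± 28.3 CPM and RpS28b from 811 ± 46.6 to 606 ± 35.6 CPM. Of 34 cell cycle genes 5 rose, 16 when adjusted over the list alone, with a median of 0.46 and an adjusted p of 1.48e-07 (adjusted p = 0.585 with an estimated correlation). Of 21 carbohydrate digestion genes 7 fell, while adjusted over the list alone 8 fell and 1 rose (adjusted p = 0.00204, and adjusted p = 0.585 with an estimated correlation). The maltase gene Mal-A1 went from 4593 ± 885 to 2135 ± 536 CPM. Of 14 nutrient transporters 3 rose, while adjusted over the list alone 4 rose and 1 fell (adjusted p = 0.0384, and adjusted p = 0.585 with an estimated correlation). Of 58 respiratory chain genes 4 rose, 7 when adjusted over the list alone (median 0.17, adjusted p = 3.19e-08, and adjusted p = 0.653 with an estimated correlation). Of 11 insulin and TOR genes 4 fell, 5 when adjusted over the list alone (adjusted p = 0.00677, and adjusted p = 0.585 with an estimated correlation), among them REPTOR-BP from 28.1 ± 1.45 to 18.2 ± 2.39 CPM. Of 24 detoxification genes 3 fell, 5 when adjusted over the list alone (adjusted p = 0.0107, and adjusted p = 0.585 with an estimated correlation). Cyp6g1 went from 314 ± 29.0 to 188 ± 12.8 CPM. Of 13 metal handling genes 2 fell, 4 when adjusted over the list alone (adjusted p = 0.0293, and adjusted p = 0.585 with an estimated correlation). The metallothionein gene MtnC went from 215 ± 76.6 to 60.6 ± 4.43 CPM. Of 20 ribosome biogenesis genes 2 fell, 3 when adjusted over the list alone (median -0.16, adjusted p = 0.00256, and adjusted p = 0.663 with an estimated correlation). Of 10 unfolded protein response genes 1 rose, 6 when adjusted over the list alone (median 0.25, adjusted p = 0.0185, and adjusted p = 0.585 with an estimated correlation). Among markers of other cells, 1 of 16 enteroendocrine markers fell, 3 when adjusted over the list alone (median -0.21, adjusted p = 0.00332, and adjusted p = 0.585 with an estimated correlation). The 7 fat body markers had a median of 1.21 (adjusted p = 0.0293, and adjusted p = 0.585 with an estimated correlation), with 0 called by edgeR, by DESeq2 or when adjusted over the list alone, and 3 higher at an unadjusted p under 0.05. The citrate synthase gene kdn rose from 549.9 ± 56.5 to 827 ± 58.7 CPM, and Mcad, a fatty acid oxidation gene that overlaps another gene on its strand, fell from 745 ± 99.2 to 355 ± 47.2 CPM. CG15199 fell from 379 ± 276 to 31.1 ± 11.8 CPM, and CG3106, which overlaps another gene on its strand, rose from 624 ± 259.9 to 1419.9 ± 80.9 CPM.

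List counts depended on the libraries and groups in the fit. With only the 2 groups compared, 24 ribosomal protein and 4 carbohydrate digestion genes fell. Carbohydrate digestion genes called lower were 2 and 1 without mated libraries 1 and 2 and 4 and 2 without unmated libraries 2 and 3. Cell cycle genes called higher were 1, 3 and 16 without mated libraries 2, 3 and 4 and 1 without unmated library 1 or 3. Of them 0 were called by edgeR without mated library 1 (8 higher at an unadjusted p under 0.05), without unmated library 2 (16 higher) or with only the 2 groups compared (15 higher).

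In all, 267 genes were higher and 354 lower of 9036 tested, against 266 called with only the 2 groups compared in the fit, where Try29F lost its call (48.7 ± 44.5 CPM unmated, 2.64 ± 0.22 CPM mated, adjusted p = 0.0555). The count was 383, 340 and 333 without mated libraries 1, 2 and 3, and 288 and 408 without unmated libraries 2 and 3.

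In the libraries labelled EcR RNAi, mated guts had higher transcripts of the mitochondrial respiratory chain and lower transcripts of carbohydrate digestion. Some ecdysone response genes were lower too, but their list as a whole did not pass the list test. Cyp28d1 fell from 304 ± 32.3 to 65.2 ± 25.8 CPM (log2 fold change -2.22, SE 0.22, adjusted p = 2.16e-04). Amyrel fell from 79.2 ± 24.5 to 11.5 ± 4.68 CPM (log2 fold change -2.78, SE 0.57, adjusted p = 0.0103), and tobi from 3431 ± 602 to 886 ± 441 CPM. CG4830, CG8468 and vanin-like rose, vanin-like from 96.5 ± 42 to 323 ± 146 CPM (log2 fold change 1.74, SE 0.38, adjusted p = 0.012). EcR itself fell (-0.43, SE 0.11, adjusted p = 0.025).

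Of 58 respiratory chain genes 41 rose, 55 when adjusted over the list alone, with a median log2 fold change of 0.29 and an adjusted p of 6.62e-21 (adjusted p = 0.69 with an estimated correlation). UQCR-6.4 of complex III rose from 48.6 ± 1.34 to 67.3 ± 7.12 CPM and ND-13A of complex I from 43.7 ± 0.83 to 56.7 ± 5.14 CPM. Of 21 carbohydrate digestion genes 12 fell and 1 rose, 13 and 2 when adjusted over the list alone (median -0.61, adjusted p = 6.32e-05, and adjusted p = 0.74 with an estimated correlation). Mal-A1 fell from 8539 ± 838 to 3981 ± 1304 CPM, while LManII rose from 977 ± 146 to 1838 ± 263 CPM. Of 30 digestive proteases 3 rose, while adjusted over the list alone 9 rose and 1 fell (median 0.55, adjusted p = 2.07e-06, and adjusted p = 0.771 with an estimated correlation). Of 17 ecdysone response genes 4 fell, including Eip74EF from 27.0 ± 3.91 to 18.7 ± 2.52 CPM and Eip93F from 155 ± 17.1 to 113 ± 10.5 CPM. Adjusted over the list alone 6 fell and 2 rose, and the list as a whole did not pass (adjusted p = 0.224). With mating in whole guts 1 of 15 tested ecdysone response genes rose and 1 fell, and the list did not pass there either (adjusted p = 0.23). Of 24 detoxification genes 5 fell, 6 when adjusted over the list alone (adjusted p = 0.0125, and adjusted p = 0.802 with an estimated correlation). In 80 ribosomal protein genes the shift was small (median -0.18, adjusted p = 1.12e-08, and adjusted p = 0.856 with an estimated correlation): 1 fell and none when adjusted over the list alone, while DESeq2, adjusting over all genes, called 26 lower. The amino acid transporter gene path rose from 126 ± 10 to 184 ± 20.6 CPM and kdn from 605 ± 117 to 991 ± 122 CPM. The lipid synthesis genes bgm (204 ± 42.5 to 363 ± 55.5 CPM) and Dgat2 (11.5 ± 0.99 to 20.4 ± 5.26 CPM) rose, and the sterol binding protein gene Npc2e fell from 1222 ± 209 to 826 ± 65.1 CPM. Of 11 insulin and TOR genes 3 fell, while adjusted over the list alone 5 fell and 1 rose (median -0.29, adjusted p = 0.0194, and adjusted p = 0.69 with an estimated correlation). Of 14 nutrient transporters 3 rose and 1 fell, also when adjusted over the list alone (median 0.37, adjusted p = 0.0194, and adjusted p = 0.69 with an estimated correlation). Of 11 muscle markers 1 rose, also when adjusted over the list alone (median 0.31, adjusted p = 0.0127, and adjusted p = 0.856 with an estimated correlation).

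The respiratory chain genes called higher were 21, 8 and 21 without mated libraries 1, 3 and 4 and 4, 17 and 25 without unmated libraries 1, 2 and 4, with medians of 0.24 to 0.32 when 1 library was left out. Carbohydrate digestion genes called lower were 7 and 6 without mated libraries 1 and 3 and 6 and 7 without unmated libraries 2 and 4, and detoxification genes were 3 without mated library 1, 3 or 4 or unmated library 2 or 4.

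In all, 485 genes were higher and 489 lower of 9036 tested, and upper quartile scaling gave 727 higher and 400 lower. The count was 552, 449 and 618 without mated libraries 1, 3 and 4 and 449, 507 and 642 without unmated libraries 1, 2 and 4. The call of EcR was lost without mated library 1 or 4 or unmated library 1 or 2 (adjusted p up to 0.0912).

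**Figure D3:**
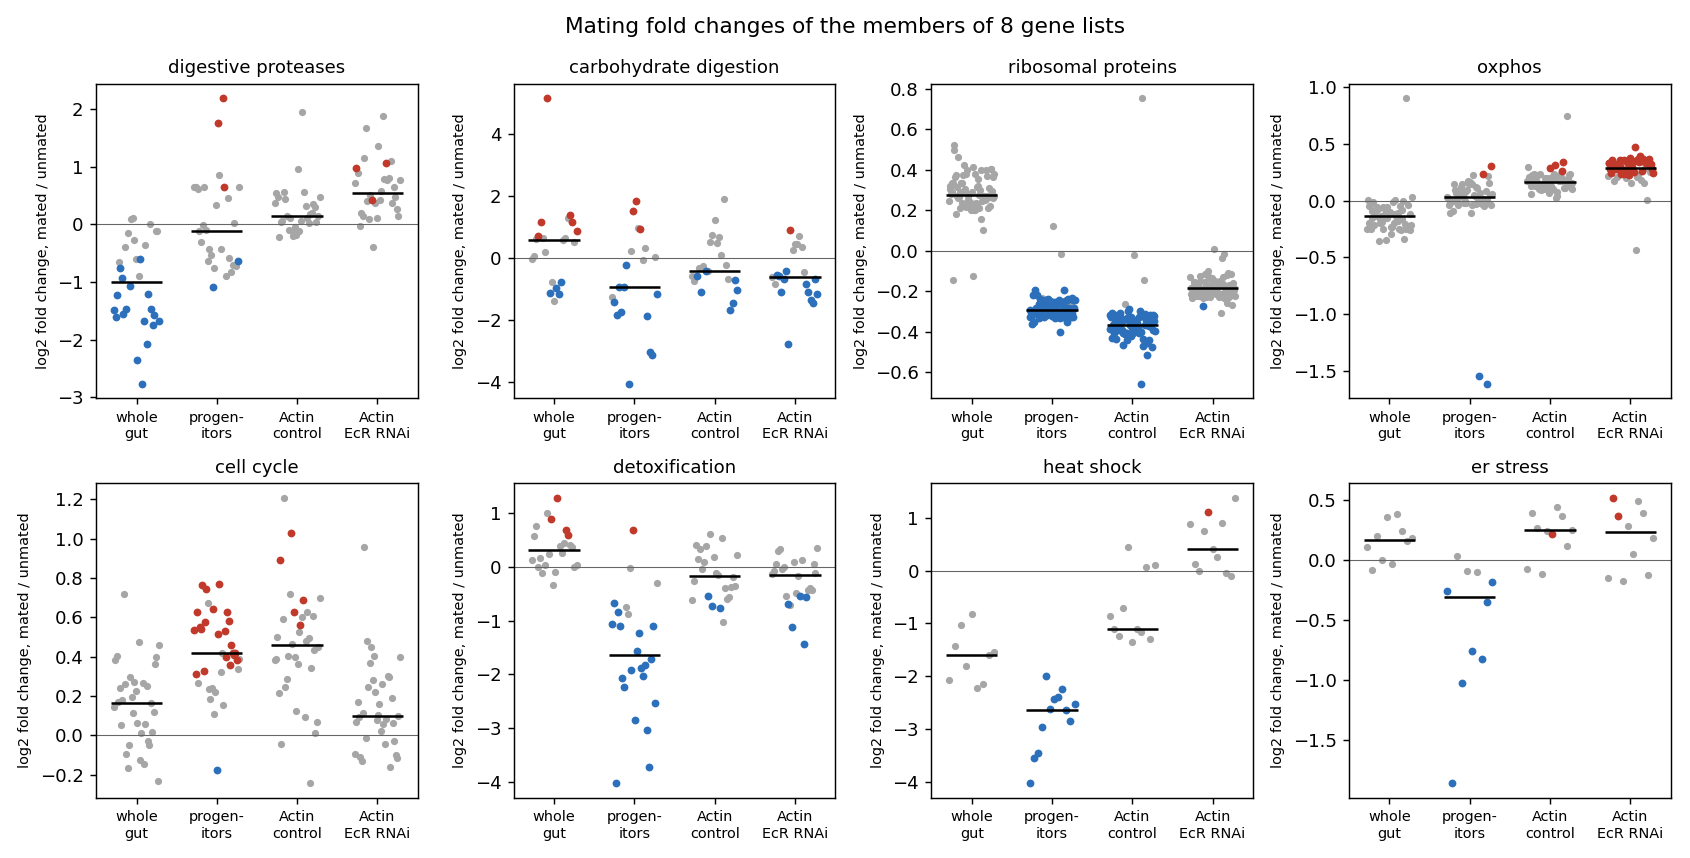
Log2 fold change, mated over unmated, of each tested member of 8 gene lists in the 4 kinds of material, with a bar at the median, called members red where higher and blue where lower, and grey members that did not pass the test. Digestive proteases have medians of -0.99 in the whole gut and 0.55 in the libraries labelled EcR RNAi, and heat shock genes a median of -2.63 in progenitors.

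The genotypes were then compared within each mating state. In unmated guts, the libraries labelled EcR RNAi had higher transcripts of unfolded protein response, detoxification and carbohydrate digestion genes, and lower transcripts of some proteases and of muscle. CG9360 (FBgn0030332; X, 11763474 to 11764590, minus strand) was at 45.6 ± 9.44 CPM in control and 1.19 ± 0.13 CPM in libraries labelled EcR RNAi, a log2 fold change of -5.26 (SE 0.21, adjusted p = 2.74e-10). Hsp70Bb (FBgn0013278; 3R, 12505793 to 12508139, plus strand), 1 of several near-identical heat shock gene copies, was at 73.2 ± 22.6 and 1.43 ± 1.19 CPM (log2 fold change -5.69, SE 0.59, adjusted p = 5.06e-05). CG11893 (FBgn0039316; 3R, 25289889 to 25291366, plus strand) had 1 count over the 4 unmated controls and 4080 over the 4 libraries labelled EcR RNAi. Amyrel rose from 3.78 ± 1.17 to 79.2 ± 24.5 CPM (log2 fold change 4.39, SE 0.62, adjusted p = 5.92e-04) and the amylase gene Amy-d, a near-identical copy of another amylase gene, from 1216 ± 489 to 4537 ± 906 CPM.

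Of 21 carbohydrate digestion genes 10 rose and 1 fell, 11 and 3 when adjusted over the list alone (median 0.71, adjusted p = 4.48e-04, and adjusted p = 0.702 with an estimated correlation). The galactosidase gene Gal rose from 398 ± 13.3 to 658 ± 96.4 CPM. Of 10 unfolded protein response genes 6 rose, 7 when adjusted over the list alone (adjusted p = 4.48e-04, and adjusted p = 0.695 with an estimated correlation): Gp93 went from 764 ± 46.4 to 1433 ± 309 CPM, Pdi from 1287 ± 20.2 to 1850.3 ± 220.4 CPM and Hsc70-3 from 1161 ± 156 to 1855 ± 507 CPM. Of 24 detoxification genes 8 rose and 1 fell, 10 and 1 when adjusted over the list alone (adjusted p = 4.48e-04, and adjusted p = 0.702 with an estimated correlation). GstE7 went from 72.1 ± 10.6 to 147 ± 34.8 CPM and GstD9 from 7.74 ± 1.89 to 21.2 ± 6.83 CPM. Of 30 digestive proteases 4 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.00265, and adjusted p = 0.825 with an estimated correlation): Ser6 fell from 361 ± 19.4 to 112 ± 20.9 CPM and Jon65Aii from 1130.4 ± 60.1 to 217 ± 87.5 CPM. CG1304, a predicted serine protease gene, fell from 194 ± 21.6 to 17.9 ± 2.50 CPM. Of 11 muscle markers 7 fell, 9 when adjusted over the list alone (adjusted p = 9.99e-05, and adjusted p = 0.702 with an estimated correlation). Mf fell from 189.5 ± 22.5 to 121 ± 8.25 CPM and up, a troponin gene, from 234 ± 42.5 to 145 ± 17.3 CPM. Of 12 progenitor markers 3 rose, 4 when adjusted over the list alone (adjusted p = 0.00265, and adjusted p = 0.702 with an estimated correlation). The gene zfh2 went from 16.8 ± 2.32 to 27.0 ± 1.03 CPM. The hormone genes Orcokinin (54.7 ± 6.98 to 28.7 ± 2.01 CPM) and NPF (36.5 ± 7.0 to 21.7 ± 1.04 CPM) were among the 4 enteroendocrine markers of 16 that fell. Adjusted over the list alone 4 fell and 1 rose (adjusted p = 0.115). Of 12 enterocyte markers 3 fell, also when adjusted over the list alone (adjusted p = 0.216), among them mex1 and the junction gene Ssk. Of 17 ecdysone response genes 1 rose, also when adjusted over the list alone (adjusted p = 0.53): br, the gene of the early ecdysone response factor Broad, from 0.65 ± 0.24 to 1.54 ± 0.12 CPM. Npc1b rose from 1196 ± 175 to 2281 ± 497 CPM, Npc2e from 737 ± 36.0 to 1222 ± 209 CPM and the isocitrate dehydrogenase gene Idh from 593 ± 21.3 to 1268 ± 301 CPM.

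Carbohydrate digestion genes called higher were 4, 6, 5 and 6 without control libraries 1 to 4 and 5 without library 2 or 4 of those labelled EcR RNAi. Muscle markers called lower were 3 and 4 without control libraries 3 and 4, and 3, 4 and 4 without libraries 1, 3 and 4 of those labelled EcR RNAi.

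In all, 718 genes were higher and 654 lower of 9036 tested in the unmated libraries labelled EcR RNAi, and upper quartile scaling gave 567 higher and 781 lower. Of 11 heat shock genes 1 fell, Hsp70Bb, also when adjusted over the list alone, and the list had a median of -1.32 (adjusted p = 0.023, and adjusted p = 0.825 with an estimated correlation). The 10 other genes of this list had a median difference of -1.31 in unmated and 0.05 in mated guts, against -5.69 and -5.81 for Hsp70Bb. Of 20 ribosome biogenesis genes 4 fell, 5 when adjusted over the list alone (median -0.25, adjusted p = 0.00161, and adjusted p = 0.825 with an estimated correlation). Of 80 ribosomal protein genes 2 fell and 1 rose, 1 and 1 when adjusted over the list alone (median -0.10, adjusted p = 0.023, and adjusted p = 0.825 with an estimated correlation).

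In mated guts some unfolded protein response, detoxification and carbohydrate digestion genes were higher in the libraries labelled EcR RNAi. CG9360 was at 38.3 ± 9.28 CPM in control and 1.38 ± 0.09 CPM in libraries labelled EcR RNAi (log2 fold change -4.79, SE 0.20, adjusted p = 7.35e-10), and Hsp70Bb at 77.2 ± 16.6 and 1.33 ± 1.47 CPM. CG11893 had 3 counts over the 4 mated controls and 2206 over the 4 libraries labelled EcR RNAi. The fucosyltransferase gene FucTC (FBgn0044872; X, 23008766 to 23011303, minus strand) rose from 5.13 ± 0.33 to 25.4 ± 1.72 CPM (log2 fold change 2.31, SE 0.15, adjusted p = 1.69e-07), having also risen in unmated guts from 6.32 ± 1.07 to 30.3 ± 7.22 CPM. The galactosidase gene Ect3 rose from 4.80 ± 1.25 to 22.5 ± 5.85 CPM and Bace, which overlaps another gene on its strand, from 3580.1 ± 279.7 to 16689 ± 2374 CPM.

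Of 10 unfolded protein response genes 5 rose, while adjusted over the list alone 6 rose and 1 fell (adjusted p = 3.57e-04, and adjusted p = 0.534 with an estimated correlation): Gp93 went from 989 ± 86.7 to 1879.5 ± 153 CPM, Pdi from 1533 ± 67.4 to 2109 ± 233 CPM and Hsc70-3 from 1524 ± 145 to 2664 ± 251 CPM. Of 24 detoxification genes 8 rose and 1 fell, 12 and 1 when adjusted over the list alone (adjusted p = 2.24e-04, and adjusted p = 0.616 with an estimated correlation). GstE7 went from 49.0 ± 5.41 to 112 ± 20 CPM. Detoxification genes called higher were 5 and 4 without control libraries 1 and 2, and 5 with only the 2 groups compared in the fit. Of 21 carbohydrate digestion genes 4 rose, while adjusted over the list alone 6 rose and 1 fell (adjusted p = 0.00237, and adjusted p = 0.866 with an estimated correlation). Amy-d went from 817 ± 275 to 2972 ± 1284 CPM and Gal from 269 ± 18.8 to 448 ± 94.1 CPM. Of 30 digestive proteases 2 rose and 2 fell, 4 and 3 when adjusted over the list alone (adjusted p = 0.649), and Ser6 fell from 314 ± 8.24 to 85.4 ± 13.7 CPM. Of 11 muscle markers 2 fell, also when adjusted over the list alone (adjusted p = 0.00924, and adjusted p = 0.866 with an estimated correlation). The ecdysone response gene br rose from 0.82 ± 0.12 to 2.23 ± 0.12 CPM, Ilp3, an insulin-like peptide gene, from 1.43 ± 0.28 to 3.45 ± 0.81 CPM and Idh from 801 ± 19.5 to 1298 ± 127 CPM. Orcokinin fell from 46.2 ± 8.90 to 31.4 ± 2.36 CPM and Ssk from 539 ± 53.6 to 397 ± 32.2 CPM. Of 24 central carbon genes 2 rose, also when adjusted over the list alone (median 0.12, adjusted p = 0.0198, and adjusted p = 0.866 with an estimated correlation), and of 80 ribosomal protein genes 1 rose, also when adjusted over the list alone (median 0.09, adjusted p = 0.00429, and adjusted p = 0.866 with an estimated correlation). Of 7 fat body markers 1 fell, 5 when adjusted over the list alone (median -2.04, adjusted p = 0.00429, and adjusted p = 0.616 with an estimated correlation). Of 5 Malpighian tubule markers 2 fell, 3 when adjusted over the list alone (adjusted p = 0.0118, and adjusted p = 0.616 with an estimated correlation), such as Irk3 from 6.65 ± 4.40 to 0.20 ± 0.14 CPM. Some transcripts varied between control libraries. Among the 4 mated controls the tubule marker Irk3 ranged from 1.05 to 10.6 CPM. CG3168, which is not a marker in this list, ranged there from 1.26 to 133 CPM, against 0.89 ± 0.24 CPM in the libraries labelled EcR RNAi.

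In all, 319 genes were higher and 451 lower of 9036 tested in the mated libraries labelled EcR RNAi, against 484 called with only the 2 groups compared in the fit and 471 without mated library 4 of those labelled EcR RNAi. The comparisons of genotype in unmated and mated guts share no library. In an overlap added after the data had been seen, 465 genes were called the same way in both (58.0 by chance), none in opposite ways (58.9 by chance). The fold changes correlated across genes with r = 0.74, where genes are not independent replicates.

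**Figure D4:**
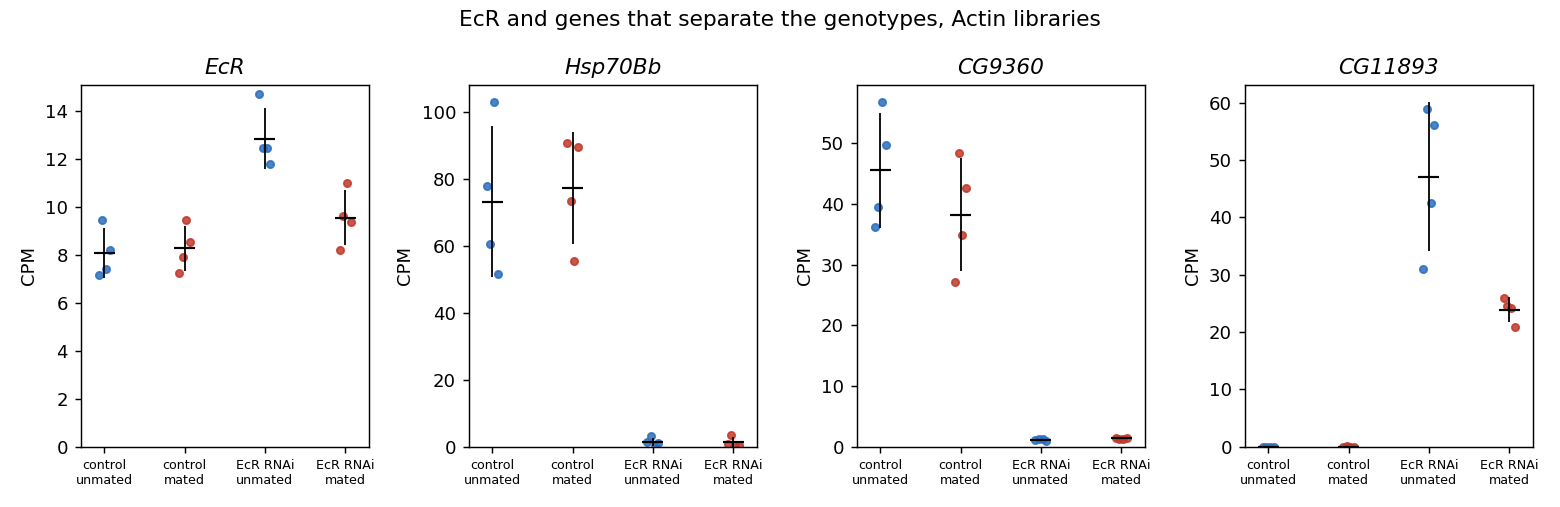
Level in CPM, on linear axes from 0, of EcR, Hsp70Bb, CG9360 and CG11893 in each Actin library, for unmated (blue) and mated (red) flies, with horizontal bars at the mean and vertical bars of 1 SD (n = 4). EcR was 8.07 CPM in unmated controls and 12.9 CPM in unmated libraries labelled EcR RNAi, and the other 3 genes were near 0 in 1 genotype.

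Whether the mating response itself differed by genotype was tested as an interaction. No gene differed at an adjusted p under 0.05 by edgeR, with 727 of 9036 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.458, while DESeq2 called 1. That gene, Tet (FBgn0263392), was chosen after its values were seen. It was at 93.1 ± 3.59 CPM in unmated and 106 ± 5.55 CPM in mated controls, and at 138.5 ± 5.69 and 116 ± 3.36 CPM in unmated and mated libraries labelled EcR RNAi. Its log2 difference was -0.43 with an adjusted p of 2.39e-04 by DESeq2 and an adjusted p of 0.458 by edgeR. EcR had an interaction of -0.47 (SE 0.16, adjusted p = 0.59). Between the mating responses of both genotypes, an overlap added after the data had been seen, 283 genes were called the same way (33.5 by chance) and none in opposite ways (33.4 by chance). Of 30 lists, 11 passed for the interaction with camera at the preset correlation and 0 with an estimated correlation (adjusted p = 0.775 for each of the 11) or by fry. In these lists 0 members were called by edgeR, by DESeq2 or when adjusted over the list alone, with 0 to 18 members of a list at an unadjusted p under 0.05. The median difference, EcR RNAi minus control, was -0.28 for 34 cell cycle genes (adjusted p = 3.82e-04), 0.18 for 80 ribosomal protein genes (adjusted p = 1.08e-13) and 0.13 for 58 respiratory chain genes (adjusted p = 2.24e-05). It was 0.32 for digestive proteases (adjusted p = 3.82e-04), 0.19 for ribosome biogenesis (adjusted p = 0.00247) and 1.27 for heat shock genes (adjusted p = 0.0426). Among cell type markers it was -1.78 for fat body (adjusted p = 0.00489), 0.21 for enteroendocrine cells (adjusted p = 0.004), 0.23 for muscle (adjusted p = 0.0233), and 0.78 for haemocytes and -0.16 for progenitors (adjusted p = 0.0426 each). With the replicate block the heat shock, haemocyte and progenitor lists lost their call.

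The mating responses of progenitors and of the whole gut were compared in a joint fit of their 16 libraries. By the labels as deposited, several of the same genes moved in opposite directions. Jon25Bii differed by 5.00 on the log2 scale (SE 0.44, adjusted p = 1.14e-05) and Alp10 by 3.75, both falling with mating in the whole gut and rising in progenitors. Amyrel differed by -9.22 (SE 0.93, adjusted p = 5.02e-05), tobi by -6.49 and Npc1b by -4.14, all rising in the whole gut and falling in progenitors, and Men differed by -1.92. Jon25Bii and tobi had lower levels in the sorted libraries than in the whole gut in both mating states. An equal share of whole gut transcripts in all sorts, with the guts as labelled, would have moved both genes the other way. For them, other kinds or shares of cells in the sorts, or exchanged whole gut labels, cannot be told apart from a change in the progenitors. Of 29 digestive proteases 12 had a higher and 1 a lower response in progenitors, also when adjusted over the list alone (adjusted p = 1.17e-07, and adjusted p = 0.568 with an estimated correlation). Of 25 detoxification genes 15 had a lower and 1 a higher response in progenitors, 18 and 2 when adjusted over the list alone (adjusted p = 4.13e-12, and adjusted p = 0.184 with an estimated correlation), with GstE7 at -4.07 (SE 0.52). Of 8 insulin and TOR genes 3 had a lower response, also when adjusted over the list alone (adjusted p = 0.00513, and adjusted p = 0.42 with an estimated correlation), with ImpL2 at -2.18 (SE 0.55, adjusted p = 0.0139).

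Other lists differed between these responses too. Of 80 ribosomal protein genes 21 had a lower response in progenitors, 69 when adjusted over the list alone (median -0.53, adjusted p = 1.83e-09, and adjusted p = 0.613 with an estimated correlation). Of 20 immune genes 5 were lower, 7 when adjusted over the list alone (median -1.68, adjusted p = 0.00391, and adjusted p = 0.184 with an estimated correlation). Of 21 carbohydrate digestion genes 9 were lower and 4 higher, 11 and 5 when adjusted over the list alone (median -1.18, adjusted p = 0.00746, and adjusted p = 0.613 with an estimated correlation). Of 19 lipid synthesis genes 7 were lower and 1 higher, 8 and 1 when adjusted over the list alone (median -0.48, adjusted p = 0.0216, and adjusted p = 0.568 with an estimated correlation). Of 15 nutrient transporters 5 were lower, while adjusted over the list alone 6 were lower and 1 higher (median -0.87, adjusted p = 0.0186, and adjusted p = 0.568 with an estimated correlation). Of 24 central carbon genes 5 were lower and 1 higher, also when adjusted over the list alone (median -0.17, adjusted p = 0.0216, and adjusted p = 0.613 with an estimated correlation). Of 10 unfolded protein response genes 5 were lower, 6 when adjusted over the list alone (median -0.46, adjusted p = 0.00899, and adjusted p = 0.568 with an estimated correlation). Of 17 enteroendocrine markers 4 were lower, also when adjusted over the list alone (median -0.58, adjusted p = 0.0216, and adjusted p = 0.568 with an estimated correlation). Of 20 ribosome biogenesis genes 5 were higher and 1 lower, 6 and 1 when adjusted over the list alone (median 0.24, adjusted p = 0.00899, and adjusted p = 0.613 with an estimated correlation). Of 58 respiratory chain genes 5 were higher and 1 lower, 0 and 1 when adjusted over the list alone (median 0.23, adjusted p = 3.96e-04, and adjusted p = 0.76 with an estimated correlation). The 35 cell cycle genes had a median of 0.30 (adjusted p = 0.0318, and adjusted p = 0.76 with an estimated correlation), with 0 called by edgeR, also when adjusted over the list alone, 4 higher and 1 lower at an unadjusted p under 0.05, and 1 lower by DESeq2. Ribosomal protein genes called lower ranged from 1 without mated whole gut library 4 to 74 without mated whole gut library 3 and were 58 by DESeq2. When 1 of the 16 libraries was left out, counts ranged from 1 to 5 for the higher respiratory chain genes, 3 to 6 for the higher ribosome biogenesis genes, 3 to 7 for the lower unfolded protein response genes, 2 to 6 for the lower immune genes and 4 to 8 for the lower central carbon genes.

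In all, 856 responses were higher and 1152 lower of 9448 genes tested.

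Mating calls, by the labels as deposited, were then compared between experiments that share no library. Whole gut and Actin control, both whole midguts, shared 3 genes called the same way (13.2 by chance) and 74 called in opposite ways (13.4 by chance), with r = -0.23 across genes by edgeR, where DESeq2 gave r = -0.0596 with 12 the same way and 176 opposite. Progenitors and Actin control shared 235 genes called the same way (118 by chance) and 56 in opposite ways (119 by chance), with r = 0.19 across genes by edgeR, where DESeq2 gave r = -0.0139. For whole gut and progenitors the counts were 40 the same way (71.7 by chance) and 115 opposite (71.6 by chance), with r = -0.18. Of 76 genes called the same way in progenitors and in both Actin genotypes, a set formed after the data had been seen, 36 were called the opposite way in the whole gut and none the same way. A score was formed from the genes called in the whole gut, as the mean log2 CPM of the higher genes minus that of the lower genes, over 196 and 179 genes. It was lower in mated than in unmated Actin controls, -1.95 ± 0.20 against -1.22 ± 0.17, a difference of -0.72 (exact two-sided permutation test, p = 0.0286, the smallest p that 4 against 4 allows), though without unmated library 2 the exact p was 0.0571. In the libraries labelled EcR RNAi it was -1.67 ± 0.08 when mated and -0.55 ± 0.11 when unmated, a difference of -1.12 (exact permutation p = 0.0286). The mated minus unmated difference was more negative by 0.40 in the libraries labelled EcR RNAi (interaction of -0.40, permutation p = 0.0155 over 4900 arrangements). In progenitors, a comparison added after the data had been seen, the score was -0.06 ± 0.18 when mated and 0.60 ± 0.22 when unmated, a difference of -0.66 (exact permutation p = 0.0286), and this exact permutation p was 0.0571 without mated library 1 (-0.61) or unmated library 3 (-0.57).

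**Figure D5:**
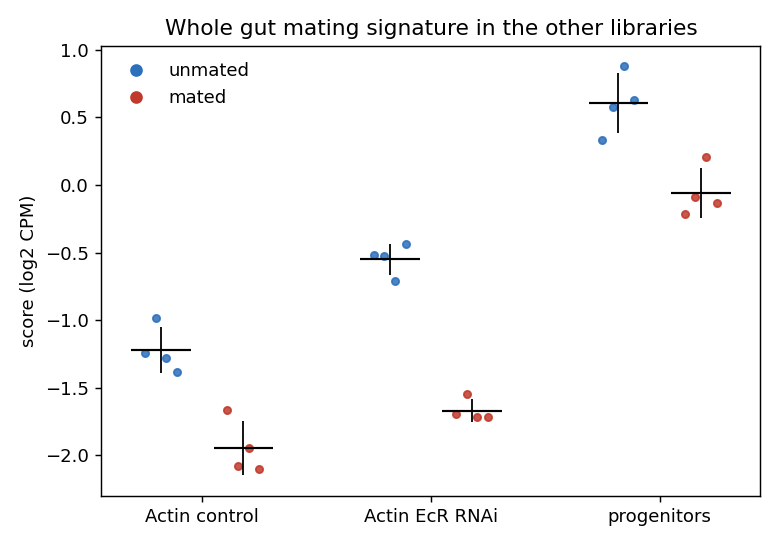
Score of the genes called in the whole gut (mean log2 CPM of genes higher in mated minus that of genes lower in mated whole guts) in each library of the other material, unmated in blue and mated in red, with horizontal bars at the mean and vertical bars of 1 SD (n = 4). The mated libraries lie below the unmated ones in Actin controls (-1.95 against -1.22), in libraries labelled EcR RNAi (-1.67 against -0.55) and in progenitors (-0.06 against 0.60).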

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

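The tests of exchanged labels, of a chromosome arm, of vector sequence and of hairpin reads, and the counts over other splits of the libraries, were chosen only after the result was seen, as were the Actin control minus whole gut difference, the score in progenitors and the set of genes called the same way in other mating comparisons, and stricter rules for reading the tests of exchanged labels, of vector sequence and of stress.

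Mating changes in the whole gut often ran opposite to those in the Actin guts and in progenitors. Genes called in opposite ways numbered 115 with progenitors (40 the same way) and 74 with Actin control (3 the same way). Still, 158 of 355 genes called in the whole gut had the same sign in progenitors. In size or direction, the responses of progenitors and whole gut differed in 2008 genes. Those of Actin control and whole gut differed in 748 genes (1155 without mated whole gut library 3, 481 without mated Actin control library 2). Progenitors minus whole gut was 5.00 for Jon25Bii, 3.75 for Alp10, -9.22 for Amyrel, -6.49 for tobi, -4.14 for Npc1b, -1.92 for Men, -4.07 for GstE7 and -2.18 for ImpL2. An axis of expression that also varies within groups was argued against for the Actin guts, as far as 3 within-group components capture it. These components held 5.91% of the variance of the fold changes in the whole gut, 6.54% in Actin EcR RNAi and 21.9% in Actin control. After removing 3 within-group components the correlation across genes with the Actin EcR RNAi response was -0.443 (-0.475 before). With the Actin control response it was -0.308 (-0.232 before). By DESeq2, without removal, these correlations were -0.244 and -0.0596. Progenitors were not tested in this way. The labels of the whole gut table were used as deposited. An exchange of mated and unmated there cannot be told apart from a difference of cohort or, against progenitors, of the cells sampled. The opposite sign was seen in 92.1% of the 76 genes called the same way in the other 3 mating comparisons. It was seen in 80.8% of the 271 called the same way in both Actin genotypes. With mated and unmated exchanged in all whole gut libraries, 74 genes differed from Actin control instead of 748, and 1416 from progenitors instead of 2008. The 10 most counted genes took 22.3% of counts in unmated and 11.4% in mated whole guts. These shares were 15.8% and 19.2% in Actin controls, 13.2% and 17.4% in libraries labelled EcR RNAi, and 9.76% and 7.67% in progenitors. A true opposite response could give such values too, and no table tests what turned it. A difference of driver was not tested and bears on the Actin guts alone, since progenitors shared the driver of the whole guts.

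The libraries labelled EcR RNAi differed from controls in genes nearly absent from 1 genotype, while EcR was not lower. A background differing on 1 chromosome arm was argued against as the whole cause, since of 26 genes called the same way in both mating states with a log2 fold change of at least 3 in size the highest percent on an arm was 30.8% (exact 95% Clopper-Pearson interval 14.3 to 51.8), though a background differing on several arms was not tested. Vector sequence of a transgene counted as Hsp70Bb cannot be told apart from a change of that gene. Against its -5.75, the 10 other heat shock genes had a median of -0.59 over both mating states. That median was -1.31 in unmated and 0.05 in mated guts. Hsp70Bb was at 73.2 and 77.2 CPM in unmated and mated controls, and at 1.43 and 1.33 CPM in libraries labelled EcR RNAi. Its copies Hsp70Aa, Hsp70Ab, Hsp70Ba and Hsp70Bc were at 0.324 to 1.88 CPM in all these groups. Sharing of reads among the copies was not measured, so these levels do not decide it. Reads of the hairpin counted as EcR cannot be told apart from a true rise of EcR: 0 ecdysone response genes of 17 were called lower by edgeR in either mating state, while 1 in unmated and 2 in mated guts were lower at an unadjusted p under 0.05 and DESeq2 called 1 and 0. A biological effect of the RNAi stays open.

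Heat shock and detoxification genes and the cytokine gene upd3 were lower in mated progenitors. More cells of other types in the unmated sorts cannot be told apart from a change within the cells: 78% of the 100 genes used as a measure of other cells were lower in mated sorts, but their totals were 2.97% of the whole gut level in mated and 2.67% in unmated sorts. Stronger stress of unmated sorts during dissociation cannot be told apart from a response to mating, because the heat shock score that measures it is made of genes of the pattern and separates the groups (7.23 to 7.93 in mated, 9.06 to 10.9 in unmated libraries). With that score as covariate the slope of adjusted on unadjusted changes, 0.236 (0.0222 without unmated library 3, 0.381 without unmated library 1), lay under the bound of 0.3 set beforehand for this explanation, but a covariate that separates the groups can lower the slope under any cause, so the bound was not used: limma called 0 genes (292 at an unadjusted p under 0.05), the median SE rose from 0.142 to 0.291 and the cell cycle median went from 0.42 to -0.33.

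Where only the real split gave as many genes, this argued against chance for that comparison taken singly. Chance was not excluded, because this is the smallest share that 35 splits allow and several comparisons were read without adjustment. Only the real split gave as many for mating in the whole gut (376, highest other 3), progenitors (3627, highest other 1), Actin control (621, highest other 531) and libraries labelled EcR RNAi (974, highest other 76). The same held for genotype in unmated (1372, highest other 2) and mated guts (770, highest other 2). In Actin control the next split parted replicates 1 and 2 from 3 and 4, so these libraries hold another structure almost as large. For the interaction edgeR called 0 genes (727 at an unadjusted p under 0.05, 1 by DESeq2), so that 100 of 100 splits had to give as many and their number says nothing about chance. The highest, 1927, exchanged mated and unmated in the libraries labelled EcR RNAi, which turns a mating response shared by both genotypes into a difference. The real split alone of 100 gave as many for progenitors minus whole gut (2008, highest other 1416) and Actin control minus whole gut (748, highest other 74). Both of these highest others were the exchange of mated and unmated in all whole gut libraries, and 3 and 5 of the other splits called any gene.

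Single libraries stood apart from the other 3 of their group in 17 of 314 groups, and chance gives about 1 in 20. The gap over the range was 0.896 for bmm in mated whole gut library 2 and 0.82905 in unmated library 1. It was 0.840 for Mlc2 in mated whole gut library 2. In progenitors it was 0.835 for GstD2 in mated library 2, 0.854 for Cyp6g1 in unmated library 4 and 0.842 for the total count of mated library 1. In the libraries labelled EcR RNAi it was 0.889 for UQCR-6.4 in mated library 3 and 0.833 in unmated library 3, 0.926 for Ser6 in unmated library 4, 0.859 for FucTC in mated library 1, 0.857 for the whole gut score in mated library 2 and 0.830 for the share of transposable elements in unmated library 3. In Actin controls it was 1 for CG11893 in unmated library 1, which held its single count, 0.845 for br in unmated library 4, 0.935 for Ect3 in mated library 1, and 0.883 for CG3168 and 0.950 for Gal in mated library 4. The response of the whole gut score differed between genotypes by -0.40. Transposable elements took 0.178% of counts in unmated and 0.0964% in mated progenitors (exact permutation p = 0.0286, adjusted p = 0.0857). They took 0.0709% in unmated Actin controls and 0.0595% in unmated libraries labelled EcR RNAi (exact permutation p = 0.0286, adjusted p = 0.0857).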

How the results depend on the processing

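Leaving out unmated progenitor libraries 1 and 4 together, Actin control minus whole gut, the score in progenitors, and the overlaps with EcR RNAi or between genotype comparisons were chosen only after the result was seen. The cause of the changes below was not tested, except that leaving out libraries or groups leaves fewer samples. With DESeq2 the called genes were 681 in the whole gut, 1042 in Actin control, 1 for the interaction, and the correlation across genes of progenitors and Actin control was -0.0139 (0.19 by edgeR). With only the 2 groups compared they were 266 in Actin control and 484 for genotype in mated guts, and without unmated progenitor libraries 1 and 4, 1302. Leaving out 1 library gave 195 to 510 in the whole gut, 2248 to 4304 in progenitors, 288 to 668 in Actin control, 449 to 1067 in libraries labelled EcR RNAi, 919 to 1292 and 471 to 639 for genotype in unmated and mated guts, 1400 to 2542 for progenitors minus whole gut and 481 to 1155 for Actin control minus whole gut. EcR, not called in these comparisons, ranged from -0.148 to 0.0133 in progenitors and from -0.0417 to 0.113 in Actin control when 1 library was left out. It changed sign in progenitors without mated library 4 (0.000285) or unmated library 1 (0.0133) and in the result mating, Actin control: EcR without mated library 3 (-0.0417), unmated library 1 (-0.0261) or unmated library 3 (-0.00944). The score difference ranged from -0.817 to -0.644 in Actin control and from -0.750 to -0.569 in progenitors when 1 library was left out, and at -0.644, -0.607 and -0.569 its exact permutation p was 0.0571. With an estimated correlation 1 list was called in the whole gut and 0 in each other comparison, against 8 to 14 with the preset one by camera. With fry 3 lists were called in the whole gut, 17 in progenitors, 2 in Actin control, 3 in libraries labelled EcR RNAi, 6 and 1 for genotype in unmated and mated guts, 12 for progenitors minus whole gut and 0 for the interaction. Genes called the same way in pairs of comparisons at an adjusted p under 0.01 numbered 8 for whole gut and progenitors, 0 for whole gut and Actin control or EcR RNAi, 15 and 30 for progenitors with these, 50 between both Actin genotypes and 192 for genotype in both mating states. With DESeq2 they numbered 113, 12, 8, 380, 326 and 517. By the labels, the libraries of a comparison share only a number. The correlation of same-numbered deviations was 0.0651 to 0.266 in Actin control and spanned 0 in the whole gut (-0.0919 to 0.284) and progenitors (-0.129 to 0.259). Of 8 libraries, 2, 3 and 4 in these comparisons were closest to their own number. In Actin control, libraries 1 and 2 correlated positively between mating states (0.193 to 0.371), as did 3 and 4 (0.0651 to 0.278). All pairs across these sets were negative (-0.398 to -0.0657). The main fits did not model this structure. With the replicate block 262 genes were called in the whole gut, 3817 in progenitors, 903 in Actin control, 1281 in libraries labelled EcR RNAi, 1590 and 889 for genotype, and 0 for the interaction by edgeR, and 8 of 11 lists held in the whole gut and for the interaction. Of the values of single genes under all alternatives 6053 kept direction and call, 763 lost the call and 5 reversed. Counts of called list members, for lists with at least 5, stayed within 1.5 times in 609 cases, and in 162 they moved further or the list's median changed sign. Of these 162, 135 arose on leaving out 1 library and 10 without unmated progenitor libraries 1 and 4, where 8 stayed.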

Other observations

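In mated progenitors 22 of 35 cell cycle genes rose and 1 fell, while 7 of 10 unfolded protein response genes, 7 of 15 nutrient transporters and 10 of 16 growth signalling genes fell and 2 of the last rose. None of these lists kept its call with an estimated correlation. All kept it with the replicate block and by fry, which does not compare a list with other genes. In the same sorts 6 ovary and 8 enteroendocrine markers fell. The heat shock score separated mated from unmated sorts, and with it as covariate the cell cycle median went from 0.42 to -0.33. A covariate that separates the groups cannot decide between stress and mating. In both Actin genotypes carbohydrate digestion genes fell with mating (7 of 21 in control, and 12 of 21 with 1 higher in libraries labelled EcR RNAi). The medians there were -0.37 and -0.18 for ribosomal protein genes and 0.17 and 0.29 for respiratory chain genes, and these lists lost their call with an estimated correlation too. Some counts moved when a library was left out: from 22 to 10 without unmated progenitor library 4, from 7 to 1 without mated Actin control library 2 and from 12 to 6 without mated library 3 of those labelled EcR RNAi. Without unmated progenitor libraries 1 and 4 together, 7 cell cycle genes were called higher. The lists were set before the result was seen, while setting them side by side was chosen only after the result was seen.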
